A study of Homo sapiens with 24 samples.

How the data were processed

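The series measured total RNA from THP-1 cells, a human monocytic leukaemia line, on 24 Affymetrix Human Gene ST arrays. Per the labels' protocols, the cells carried a lentiviral cassette in which doxycycline (DOX) switches on a FLAG-tagged NOD1 or NLRP4 coding sequence, or the empty vector. Cells were seeded at 50000 per well of a 96-well plate and received DOX at 1 µg/ml for 6 h, or no DOX. The labels place 4 arrays in each of 6 groups: vector, NLRP4 line and NOD1 line, each without and with DOX. They also state that the plate order was assigned in advance and not randomized, and they number the arrays consecutively with each line in its own block. Line and place in that order therefore cannot be told apart by a block term. Within each line the uninduced arrays are numbered before the DOX arrays, so DOX and place in the order cannot be told apart either. Nothing in the labels says that the wells of a group came from separate cultures or from separate transductions, so the p-values measure the spread between these wells, which may be technical.

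The deposited values are log2 signals, 1 per probe set and array. Per the submitters' processing notes, RMA (a background correction, normalization and summary of probes) and the oligo package were used, and their versions, the array's genome build and the order of the steps are not given in the sources used here. The deposited log2 values did not share a distribution: the array medians ran from 8.06 to 8.85. Quantile normalization between arrays, planned as an alternative, was therefore made the main setting. It was applied to the gene table with limma, and the values as deposited became an alternative. This choice was made from the array distributions before any comparison was fitted. Deposited values can carry array brightness into a comparison. The number of arrays, 4 per group, limits the precision.

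Probe sets were named from the platform annotation. Of 33297 probe sets, 19460 had a single gene symbol, 1754 had several and 12083 were unnamed here. Symbols were updated through Entrez IDs with a RefSeq gene table of assembly GRCh38.p14, in which 19429 single-symbol probe sets matched, and that table was also used for which genes neighbour each other. Probe sets with several symbols or none were left out of the main comparisons. The probe set with the highest mean over all arrays stood for its gene, which left 18417 genes, 769 of them with more than 1 probe set. No filter on dim genes was applied. No background level was measured here, so where the lower group lay near the low end of the signal the fold is given as at least that value, and the log2 changes there are lower bounds too. A probe set for NOD1 or NLRP4 does not separate the introduced sequence from the cell's own transcript. Signals of near-identical copies, such as AKR1C1 and AKR1C2, or of pseudogenes and their parents, may be mixed.

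Each gene was fitted in R 4.3.3 with limma 3.58.1 as 6 group means over all 24 arrays, which leaves 18 residual degrees of freedom, followed by empirical Bayes moderation with its default prior. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. The 8 comparisons were DOX against no DOX within each line, the 3 differences between those DOX effects, and each uninduced line against the uninduced vector line. For NOD1 and NLRP4 a two-sided exact permutation test of 4 arrays against 4 was added, whose smallest possible p is 0.0286. Before the data were examined, 24 gene lists with 831 entries were written. Of these entries 735 were measured, and the list of mitochondrially encoded transcripts had too few measured genes to be tested, which left 23 lists. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data, with adjustment over the lists of a comparison. Adjusted p-values below are limma's unless a list test is named.

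The genes named were also chosen by a rule fixed before the data were examined. It takes NOD1 and NLRP4. It then takes, among called genes whose 4 arrays of one group all lie above the 4 of the other, the 12 largest rises and the 12 largest falls. For a called list it takes up to 4 called members with the lowest p. Where fewer than 6 genes were called, it takes those and the 5 with the lowest p. Genes named outside this rule are marked as chosen after their values were seen.

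The fit and the list test were tested on simulated arrays built from the measured means, residual spread and array distributions, with 200 of 18417 genes changed in each of 10 simulations. For DOX in the NOD1 line, 65.8% of genes changed by 0.5 on the log2 scale, 97.2% of those changed by 1 and 99.4% of those changed by 2 were called, and 4.1% of calls were false. For the uninduced NOD1 line against the vector line the shares were 64.3%, 96.6% and 99.4%, with 5.3% of calls false. For the DOX effect of the NOD1 line minus that of the vector line they were 28.4%, 87.1% and 98.9%, with 4.7% of calls false. A list of 40 genes shifted by 0.2 was found in 10 of 10 simulations of each at an unadjusted camera p under 0.05, and an unshifted list in 0 of 10. Genes were simulated independently of each other. The list simulations therefore do not cover correlated lists, such as oxidative phosphorylation genes with an estimated correlation of 0.18. Rises and falls were simulated as equally likely and in 200 genes only. For the uninduced NOD1 line against the vector line 4592 genes were called in the real data. The rates simulated for that comparison therefore do not carry over to it.

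Alternatives planned before the data were examined were a filter on dim genes (mean log2 of at least 5, or above the median gene), the average of a gene's probe sets, all probe sets tested by ID, arrays centred on their medians, a trended robust prior, array weights, only the arrays compared, an adjusted p under 0.01, a 1.5-fold minimum, limma's treat test against 1.1-fold, position within a group as a covariate, fry for the lists, and leaving out each array. Alternatives added afterwards were the values as deposited, quantile normalization over all probe sets, the array median as a covariate, leaving out the 4 arrays with the lowest deposited medians, the line comparisons on the DOX arrays, the NLRP4 line as the comparator, and, for the splits of the arrays, leaving NOD1 and NLRP4 out of the genes tested.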

Results

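Gene expression was measured in THP-1 cells, a monocytic leukaemia line, that carried a doxycycline (DOX)-inducible NOD1 or NLRP4 coding sequence or the empty vector. NOD1 is a cytosolic sensor of bacterial peptidoglycan fragments that signals through RIPK2 to NF-kB and MAP kinases. NLRP4 is another member of the NOD-like receptor family. Each of the 6 combinations of line and DOX treatment had 4 arrays, and 18417 genes were tested. Pairs of arrays of the same group correlated at 0.982 to 0.993 across genes, and no pair was closer than an SD of differences of 0.208 on the log2 scale. The deposited array medians averaged from 8.47 ± 0.0988 (SD, n = 4) in the uninduced NLRP4 line to 8.79 ± 0.0490 (SD, n = 4) in the DOX-treated NLRP4 line. In the deposited values the median gene stood at 0.26 with DOX in the NLRP4 line and at −0.30, 0.15 and −0.12 for the DOX effects of the NOD1 minus NLRP4, NLRP4 minus vector and NOD1 minus vector lines. Changes below are relative to the normalized distribution.

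The induced genes were examined first, since they check the labels. NOD1 stood at 8.33 ± 0.19 (SD, n = 4) on the log2 scale in the uninduced vector line, 8.74 ± 0.19 in the uninduced NOD1 line and 12.75 ± 0.18 in the NOD1 line with DOX. NLRP4 stood at 6.92 ± 0.33 in the uninduced vector line, 8.09 ± 0.43 in the uninduced NLRP4 line and 11.93 ± 0.26 in the NLRP4 line with DOX. DOX raised NOD1 16.2-fold in the NOD1 line (log2 change 4.02, SE 0.135, limma adjusted p = 7.39e-16) and NLRP4 14.3-fold in the NLRP4 line (3.84, SE 0.188, adjusted p = 3.73e-12). All 4 DOX arrays lay above the 4 uninduced arrays in both cases, with an exact permutation p of 0.0286, the smallest the design can give. Induction was specific to the line: DOX changed NOD1 by 0.06 (SE 0.135, adjusted p = 0.999) in the vector line and by 0.23 (SE 0.135, adjusted p = 0.686) in the NLRP4 line, and the rise in the NOD1 line exceeded these by 3.95 (SE 0.190, adjusted p = 2.61e-12) and 3.79 (SE 0.190, adjusted p = 6.87e-12). Without DOX, NLRP4 was already at least 2.25-fold above the vector line in its own line (log2 1.17, SE 0.188, adjusted p = 0.0405), and NOD1 was 1.32-fold above it in its own line (log2 0.40, SE 0.135, adjusted p = 0.0299, exact permutation p = 0.0571). The call for NOD1 was lost with arrays centred on their medians (0.38, adjusted p = 0.0567) and without vector_noDOX replicate 1 or 3 or NOD1_noDOX replicate 1 or 4, where it ranged from 0.35 to 0.36. The call for NLRP4 was lost in the values as deposited (1.05, adjusted p = 0.659), with only the arrays compared (1.17, adjusted p = 0.529), and without vector_noDOX replicate 2, 3 or 4 or NLRP4_noDOX replicate 3 or 4, where it ranged from 1.00 to 1.21.

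**Figure D1:**
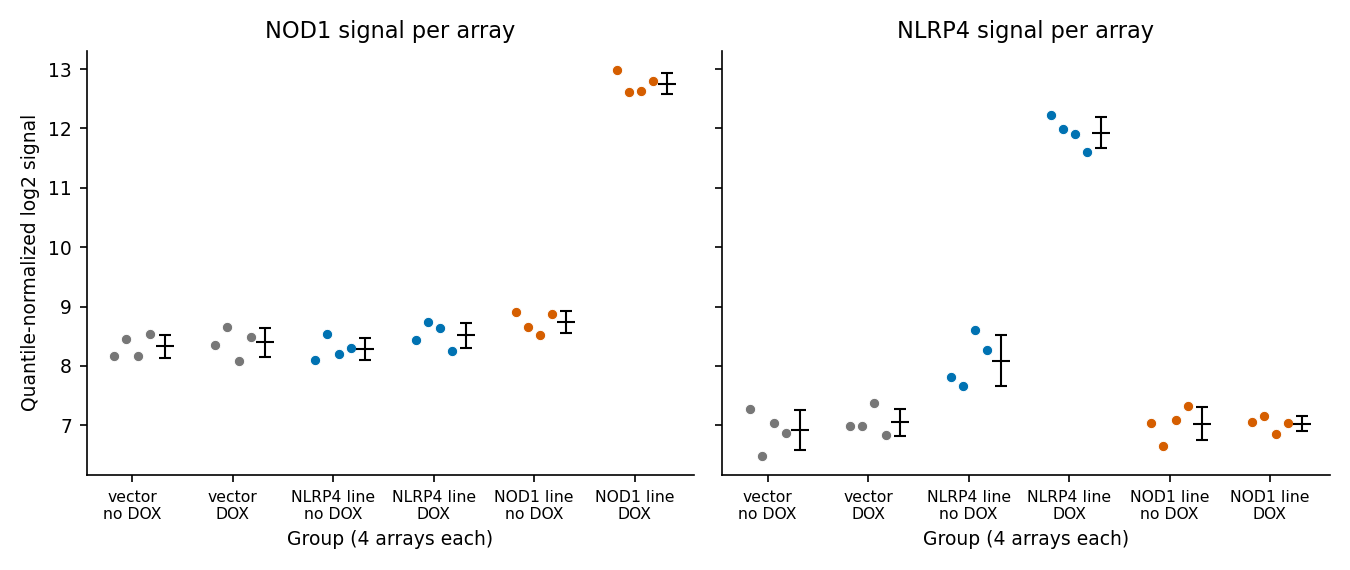
NOD1 (left) and NLRP4 (right) signal on each array, in quantile-normalized log2 units, for the 6 groups of 4 arrays. Points are arrays, and the bar beside them is the mean with its SD. The DOX-treated NOD1 line averages 12.75 for NOD1 and the DOX-treated NLRP4 line 11.93 for NLRP4, and every other group averages between 6.92 and 8.74.

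The comparison of DOX with no DOX in the NOD1 line asks which genes respond within 6 h to raised NOD1. Besides NOD1, KLHL5, a BTB-kelch protein, was the other of 2 called genes and rose 1.77-fold (log2 0.83, SE 0.116, adjusted p = 0.00239). KLHL5 started low in the NOD1 line, at 9.06, and reached 9.89 with DOX. It stayed below the vector line (10.40 without and 10.37 with DOX) and the NLRP4 line (10.14 and 10.18). The genes with the next lowest p were not called: LONRF3 at −0.47 (SE 0.084, adjusted p = 0.0608), the ceramide synthase gene CERS5 at 0.82 (SE 0.158, adjusted p = 0.129) and USP6NL at 0.90 (SE 0.179, adjusted p = 0.129). LONRF3 was called without NOD1_noDOX replicate 3 or 4 (adjusted p = 0.0393 and 0.0161), and CERS5 and USP6NL without NOD1_noDOX replicate 3 (adjusted p = 0.0471 for both) or NOD1_DOX replicate 2 (adjusted p = 0.0319 and 0.0295). CERS5 went from 8.57 to 9.39 in the NOD1 line, but also from 8.72 to 9.27 in the vector line and from 8.71 to 9.17 in the NLRP4 line. USP6NL went from 8.56 to 9.46 in the NOD1 line, while the groups of the other lines averaged 9.45 to 9.78. Inflammatory targets did not pass the test. Of 29 measured NF-kB feedback and survival genes 0 were called over all genes, and 2 were lower when adjusted over the list alone, with a list median of 0.00 (camera adjusted p = 0.594). Of 35 cytokine and chemokine genes 0 were called over all genes and 0 when adjusted over the list alone, with a median of −0.03 (camera adjusted p = 0.594). Of 36 immediate early and MAPK feedback genes 0 were called by either count (camera adjusted p = 0.594). An unadjusted p under 0.05 was reached by 1062 of 18417 genes, or 5.77%. KLHL5 was not called with only the arrays compared (0.83, adjusted p = 0.249) or in the values as deposited (0.80, adjusted p = 0.0610).

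Camera called 2 lists upward in that comparison. The 38 measured interferon-stimulated genes had a median of 0.11 (camera adjusted p = 0.0145, and adjusted p = 0.544 with an estimated correlation), with 25 members above 0, 0 called over all genes and 1 higher when adjusted over the list alone. Examples, chosen after their values were seen, are SAMD9 at 0.67 (SE 0.150, adjusted p = 0.249) and OAS2, a 2'-5'-oligoadenylate synthetase, at 0.50 (SE 0.171, adjusted p = 0.692). SAMD9 went from 9.09 to 9.77 in the NOD1 line and stayed below the DOX-treated vector (10.99) and NLRP4 (10.97) lines. The 43 G2/M genes had a median of 0.07 (camera adjusted p = 0.0145, and adjusted p = 0.544 with an estimated correlation), with 32 members above 0 and 0 called by either count. Without the 4 dimmest arrays the G2/M list was no longer called (0.04, camera adjusted p = 0.506). The gene count rose from 2 to 8 without NOD1_noDOX replicate 3 or 4, to 4 without NOD1_noDOX replicate 2 or NOD1_DOX replicate 2, and fell to 1 with only the arrays compared, in the values as deposited and without the 4 dimmest arrays. The list count fell from 2 to 1 without NOD1_DOX replicate 1, 3 or 4.

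DOX in the NLRP4 line called NLRP4 and 2 further genes. HSD3BP4, a pseudogene of the 3-beta-hydroxysteroid dehydrogenase family, rose at least 1.87-fold (log2 0.91, SE 0.154, adjusted p = 0.0296), and METTL23, a methyltransferase gene, fell by 0.58 (SE 0.098, adjusted p = 0.0296). Next by p were TTC27 at −0.39 (SE 0.079, adjusted p = 0.222) and the transcription factor gene PAX6 at 0.50 (SE 0.104, adjusted p = 0.279), both called without NLRP4_DOX replicate 4 (−0.44 and 0.58, adjusted p = 0.0450 and 0.0446). Cholesterol synthesis and SREBP target genes were the called list, with a median of 0.18 over 26 genes, 23 of them above 0 (camera adjusted p = 5.12e-05, and adjusted p = 0.0996 with an estimated correlation). Of these 26 genes 0 were called over all genes and 0 when adjusted over the list alone. Members chosen after their values were seen include NSDHL at 0.26 (SE 0.111, adjusted p = 0.579) and SREBF2, which encodes a master regulator of the pathway, at 0.28 (SE 0.132, adjusted p = 0.617). HSD3BP4 and METTL23 were not called with only the arrays compared (adjusted p = 0.143 and 0.273), in the values as deposited (1.20 and −0.26, adjusted p = 0.0861 and 0.129) or with the array median as a covariate (0.62 and −0.49, adjusted p = 0.476 for both). With arrays centred on their medians the list median turned to −0.08 against −0.06 for all genes (camera adjusted p = 0.761), and in the values as deposited it was 0.24 against 0.26 (camera adjusted p = 0.744). The gene count fell from 3 to 1 without NLRP4_noDOX replicate 1 or 2 or NLRP4_DOX replicate 1, 2 or 3, and rose to 8 without NLRP4_DOX replicate 4, and the list count rose from 1 to 3 without NLRP4_DOX replicate 1 and to 2 without NLRP4_DOX replicate 2 or 4.

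DOX itself was examined in the vector line, which has no inducible gene. No gene was called by limma, and 622 genes, 3.38% of those tested, reached an unadjusted p under 0.05. The lowest p belonged to the bitter taste receptor gene TAS2R40 at 0.91 (SE 0.169, adjusted p = 0.348), the readthrough pseudogene PDXDC2P-NPIPB14P at −0.78 (SE 0.164, adjusted p = 0.827), the protease gene ADAMTS1 at 0.49 (SE 0.111, adjusted p = 0.912), ZNHIT2 at 0.41 (SE 0.093, adjusted p = 0.912) and TSSK3 at 0.46 (SE 0.113, adjusted p = 0.999). Of the 23 lists 0 were called, the lowest camera adjusted p being 0.241. With array weights 1 gene was called, and with arrays centred on their medians or in the values as deposited 3 lists were called. Without vector_noDOX replicate 1 or 4, 1 list was called. A DOX effect common to the 3 lines was not tested, so these counts hold for the vector line only.

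The differences between DOX effects test whether a response belongs to 1 line. NOD1 was the gene called for the NOD1 line minus the vector line, and NLRP4, with 3.71 (SE 0.266, adjusted p = 1.43e-08), was the gene called for the NLRP4 line minus the vector line. For the NOD1 line minus the NLRP4 line the 2 called genes were NOD1 at 3.79 and NLRP4 at −3.84 (SE 0.266, adjusted p = 3.47e-09). KLHL5 did not pass when set against the vector line (0.85, SE 0.164, adjusted p = 0.234), although it did without NOD1_noDOX replicate 4 (0.96, adjusted p = 0.0228). LONRF3 at −0.60 (SE 0.119, adjusted p = 0.255), USP6NL at 1.23 (SE 0.253, adjusted p = 0.299) and the calgranulin gene S100A12 at 2.83-fold (SE 0.342 on the log2 scale, adjusted p = 0.730) did not pass either. For the NLRP4 line minus the vector line, SNORD58A stood at −1.14 (SE 0.211, adjusted p = 0.152), the cell cycle kinase gene CDK1 at −0.61 (SE 0.123, adjusted p = 0.290), TTC27 at −0.52 (SE 0.112, adjusted p = 0.482) and USP32P1 at −1.26 (SE 0.276, adjusted p = 0.482). For the NOD1 line minus the NLRP4 line, SNORD58A stood at 1.14 (SE 0.211, adjusted p = 0.104), C2orf81 at −0.53 (SE 0.103, adjusted p = 0.122) and RPRD1B at 0.69 (SE 0.135, adjusted p = 0.122). SNORD58A was called in both with arrays centred on their medians, at −1.34 (adjusted p = 0.00398) and 1.36 (adjusted p = 0.00190), and in the latter without NOD1_noDOX replicate 2 (1.28, adjusted p = 0.00848), where RPRD1B was called too (0.78, adjusted p = 0.0188). Without that array or NOD1_DOX replicate 1 the latter count rose from 2 to 4.

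Among the lists, 0 were called for either line minus the vector line, but 5 and 7 were called for the NOD1 line with centred arrays and in the values as deposited, and 6 and 6 for the NLRP4 line. For the NOD1 line 2 were called without NOD1_noDOX replicate 2 and 1 without vector_noDOX replicate 1 or 4, and for the NLRP4 line 1 without vector_noDOX replicate 4. For the NOD1 line minus the NLRP4 line, G2/M genes had a median of 0.08 (camera adjusted p = 0.0458, and adjusted p = 0.521 with an estimated correlation) and cholesterol synthesis genes a median of −0.16 (camera adjusted p = 0.0458, and adjusted p = 0.521 with an estimated correlation). Of their members 0 were called over all genes, and adjusted over the list alone 1 G2/M gene was higher and 0 cholesterol genes were called. The cholesterol list turned upward against all genes in the values as deposited (−0.24 against −0.30, camera adjusted p = 0.822) and with centred arrays (0.12 against 0.07, camera adjusted p = 0.771). The number of lists called fell to 0 or 1 in 11 of 16 fits that left out an array.

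The uninduced NOD1 line differed widely from the uninduced vector line, while its NOD1 level was 1.32-fold higher. Limma called 4592 of 18417 genes (24.9%), 2399 higher and 2193 lower in the NOD1 line, and 407 of them differed at least 2-fold, 73 higher and 334 lower. Among the largest rises were ALX1, a homeobox gene (at least 13.2-fold, log2 3.72, SE 0.253), BEX5 (at least 5.83-fold, 2.54, SE 0.158), the calgranulin gene S100A8 (4.77-fold, 2.25, SE 0.274), the stem cell factor receptor gene KIT (at least 3.70-fold, 1.89, SE 0.134) and the caveolin gene CAV1 (3.56-fold, 1.83, SE 0.134). The 3 largest falls were PPP1R3A, a glycogen-targeting phosphatase subunit gene (at least 10.7-fold lower, log2 −3.42, SE 0.144), the kinase gene CDC42BPA (9.11-fold lower, −3.19, SE 0.134) and the adhesion molecule gene NCAM1 (5.66-fold lower, −2.50, SE 0.140). The adjusted p of these 8 genes was at most 1.49e-06. Their 4 arrays of each line were fully separated, as the rule that chose them required. PPP1R3A stood at 10.19 ± 0.18 (SD, n = 4) in the vector line and 6.77 ± 0.25 (SD, n = 4) in the NOD1 line.

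Other large rises were TSPYL5 (1.88, SE 0.219), PIP5K1A (1.83, SE 0.221), the interferon-induced GTPase gene MX1 (1.74, SE 0.205), ZNF439 (1.74, SE 0.205), LINC01140 (1.68, SE 0.305), the lysophospholipid transporter gene MFSD2A (1.60, SE 0.123) and VIT (1.53, SE 0.135). Other large falls were EYS (−2.40, SE 0.281), ZNF215 (−2.30, SE 0.173), ANKRD26 (−2.12, SE 0.131), TCAF1 (−2.12, SE 0.321), DPP10 (−2.07, SE 0.136), CCDC88A (−2.01, SE 0.151), the pseudogenes TMEM14EP (−1.90, SE 0.275) and ZNF847P (−1.88, SE 0.520), and PELO (−1.85, SE 0.409). Where a gene had several probe sets these did not always move alike. For EYS the other 4 probe sets lay between −0.26 and 0.14 and were not called, and for TCAF1 1 other probe set fell by 0.96 and 1 stood at 0.26 without a call. The second probe set of LINC01140 rose by 0.31, against 1.75 for the one used in the same fit.

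Of 27 measured oxidative stress (NRF2) and metallothionein genes, 17 were higher in the uninduced NOD1 line and 0 lower over all genes, and 20 and 0 when adjusted over the list alone, with a median of 0.51 (camera adjusted p = 9.84e-10, and adjusted p = 0.000273 with an estimated correlation). Those higher included the pentose phosphate enzymes PGD (0.92, SE 0.092) and TALDO1 (0.76, SE 0.089), the aldo-keto reductase AKR1C1 (1.53, SE 0.161) and the ferritin light chain FTL (0.74, SE 0.083), and, chosen after their values were seen, the metallothioneins MT1F (0.66, SE 0.097) and MT2A (0.43, SE 0.105). A second probe set of AKR1C1 rose by 0.45. Of amino acid and integrated stress response (ATF4) genes 16 of 37 were higher and 4 lower over all genes, and 17 and 4 when adjusted over the list alone, with a median of 0.20 (camera adjusted p = 0.000289, and adjusted p = 0.0191 with an estimated correlation). The alanyl-tRNA synthetase AARS1 (0.91, SE 0.099) and the amino acid transporters SLC3A2 (0.97, SE 0.117), SLC1A5 (0.87, SE 0.115) and SLC7A1 (0.88, SE 0.126) were higher. For SLC1A5 a second probe set stood at 0.18 without a call. In the unfolded protein and heat shock list 9 of 28 genes were higher and 0 lower, and 9 and 2 when adjusted over the list alone. Those higher included HYOU1 (1.23, SE 0.117), MANF (0.59, SE 0.095), CRELD2 (0.57, SE 0.094) and PDIA4 (0.47, SE 0.087). PDIA4 was not called with arrays centred on their medians (0.36, adjusted p = 0.1). The list median was 0.14 (camera adjusted p = 0.0304, and adjusted p = 0.0927 with an estimated correlation).

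Monocyte and macrophage genes also differed, with 20 of 49 higher and 3 lower over all genes, 22 and 3 when adjusted over the list alone, and a median of 0.21 (camera adjusted p = 0.000331, and adjusted p = 0.0134 with an estimated correlation). The lysosomal marker CD68 (1.19, SE 0.129), S100A8 and the azurophil granule protein AZU1 (0.87, SE 0.112) were higher, while the endotoxin receptor TLR4 fell by 1.12 (SE 0.155). Nuclear-encoded oxidative phosphorylation genes had 15 of 41 higher and 0 lower, and 16 and 0 when adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.00104, and adjusted p = 0.302 with an estimated correlation). NDUFV1 of complex I (1.17, SE 0.133), CYC1 (0.90, SE 0.130) and UQCRC2 (0.50, SE 0.079) of complex III and NDUFB10 of complex I (0.43, SE 0.084) led this list. With arrays centred on their medians UQCRC2 (0.37, adjusted p = 0.173) and NDUFB10 (0.295, adjusted p = 0.228) were not called. Immediate early and MAPK feedback genes had 9 of 36 higher and 2 lower, and 11 and 2 when adjusted over the list alone, with a median of 0.17 (camera adjusted p = 0.0176, and adjusted p = 0.0233 with an estimated correlation). JUN (0.66, SE 0.104), MCL1 (0.35, SE 0.085) and DUSP6 (0.57, SE 0.141) were higher, and SPRED1, an inhibitor of RAS signalling, fell by 1.21 (SE 0.185). MCL1 was not called with arrays centred on their medians (0.20, adjusted p = 0.355), nor DUSP6 on the DOX arrays (0.37, adjusted p = 0.0532).

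G2/M cell cycle genes formed the list called downward, with a median of −0.12 (camera adjusted p = 0.000157, and adjusted p = 0.0252 with an estimated correlation). Of 43 measured, 20 were lower and 7 higher over all genes, and 20 and 9 when adjusted over the list alone. The spindle and kinetochore genes KIF20B (−1.78, SE 0.164), ASPM (−1.72, SE 0.139), CENPF (−1.46, SE 0.118) and HMMR (−1.04, SE 0.092) were lower. The 7 higher members went the other way, among them, chosen after their values were seen, the anaphase activator CDC20 (0.94, SE 0.096) and the mitotic kinase PLK1 (0.57, SE 0.130). S phase genes were not called as a list by camera (12 of 38 higher, 5 lower, 13 and 5 when adjusted over the list alone, median 0.17, camera adjusted p = 0.116). Whether the called lists of this line follow transcript length or base composition was not tested.

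The inflammatory lists were not called by camera against the vector line in the uninduced NOD1 line. Fry, which does not set a list against the other genes, called 17 of the 23 lists there. It called upward the NF-kB (fry adjusted p = 6.29e-07), cytokine (0.0026), interferon-stimulated (0.0394) and NOD-like receptor (0.00143) lists. Of all genes tested 24.9% were called. NF-kB feedback and survival genes had 7 of 29 higher and 3 lower by both counts, with a median of 0.18 (camera adjusted p = 0.116). Cytokine and chemokine genes had 2 of 35 higher and 0 lower by both counts, with a median of 0.07 (camera adjusted p = 0.622). The 2 were TNF (0.79, SE 0.138, adjusted p = 0.000129) and IL1B (0.86, SE 0.195, adjusted p = 0.00173), and NFKBIA, the NF-kB inhibitor, rose by 1.18 (SE 0.145, adjusted p = 1.74e-06), all 3 chosen after their values were seen. Interferon-stimulated genes moved in both directions, with 12 of 38 higher and 7 lower, and 16 and 7 when adjusted over the list alone (median 0.19, camera adjusted p = 0.285). MX1 was among those higher, and SAMD9, chosen after its value was seen, fell by 1.81 (SE 0.150). NOD-like receptor and inflammasome components had 9 of 35 higher and 8 lower, and 10 and 12 when adjusted over the list alone (camera adjusted p = 0.792). Against the uninduced NLRP4 line, a comparator added after the data were seen, 11 lists were called, of which 2 (oxidative stress and monocyte genes) kept their call with an estimated correlation. They included NF-kB feedback and survival genes (median 0.14, 10 of 29 higher and 1 lower over all genes, 12 and 3 over the list alone, camera adjusted p = 0.0313, and adjusted p = 0.0569 with an estimated correlation). Interferon-stimulated genes were called as well (median 0.27, 15 of 38 higher and 6 lower, 16 and 6 over the list alone, camera adjusted p = 0.0313, and adjusted p = 0.278 with an estimated correlation), and cytokines and chemokines were not (camera adjusted p = 0.201).

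For the lists not described so far camera's adjusted p lay between 0.102 and 0.935. They were proto-oncogenes and growth factors (median 0.09), p53 targets and apoptosis (0.07), antigen presentation (0.05), cholesterol synthesis (0.04), glycolysis and hypoxia (0.03), cytosolic ribosomal proteins (0.02) and replication-dependent histones (0.00). Markers of other cell types had medians of 0.07 for T and NK cells, 0.02 for B and plasma cells, 0.01 for erythroid cells and megakaryocytes and −0.03 for epithelial cells, fibroblasts and HEK-293 cells, and at most 2 genes of such a list were called. The directions of the 7 called lists were the same with arrays centred on their medians and in the values as deposited. With centred arrays the medians of oxidative phosphorylation (from 0.16 to 0.03, camera adjusted p = 0.0657) and of the unfolded protein and heat shock list (from 0.14 to 0.03, camera adjusted p = 0.0865) shrank and neither was called, and the latter was also lost without vector_noDOX replicate 3 (camera adjusted p = 0.0627).

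The same lines on the DOX arrays, which share no array with the uninduced groups, gave 4746 called genes. Of the 4592 genes called without DOX, 3512 were called the same way with DOX and 2 the opposite way. Genes called higher in both numbered 1749 and genes called lower in both 1763, against 326 and 267 for independent lists of these sizes. The differences correlated across genes at r = 0.871 and rho = 0.760, where genes are not independent replicates. Of the 7 lists 6 were called with DOX, of which 4 kept their call with an estimated correlation. Oxidative phosphorylation genes had a median of 0.22 (camera adjusted p = 2.7e-05, and adjusted p = 0.191 with an estimated correlation). G2/M genes had a median of −0.17 there (camera adjusted p = 0.00106, and adjusted p = 0.0655 with an estimated correlation), and immediate early and MAPK feedback genes, at 0.11, were not called (camera adjusted p = 0.177). PPP1R3A stood at −3.63, ALX1 at 3.34 and S100A8 at 2.05 there, while IL1B stood at 0.16 (adjusted p = 0.627) and TNF at 0.35 (adjusted p = 0.0672) and were not called. The split into higher and lower calls depended on the scaling: with arrays centred on their medians 1398 genes were higher and 2433 lower, and with quantile normalization over all probe sets 3456 were higher and 2012 lower. Each line was 1 block of the sample numbering, so the differences between lines cannot be separated from plate position or handling.

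**Figure D2:**
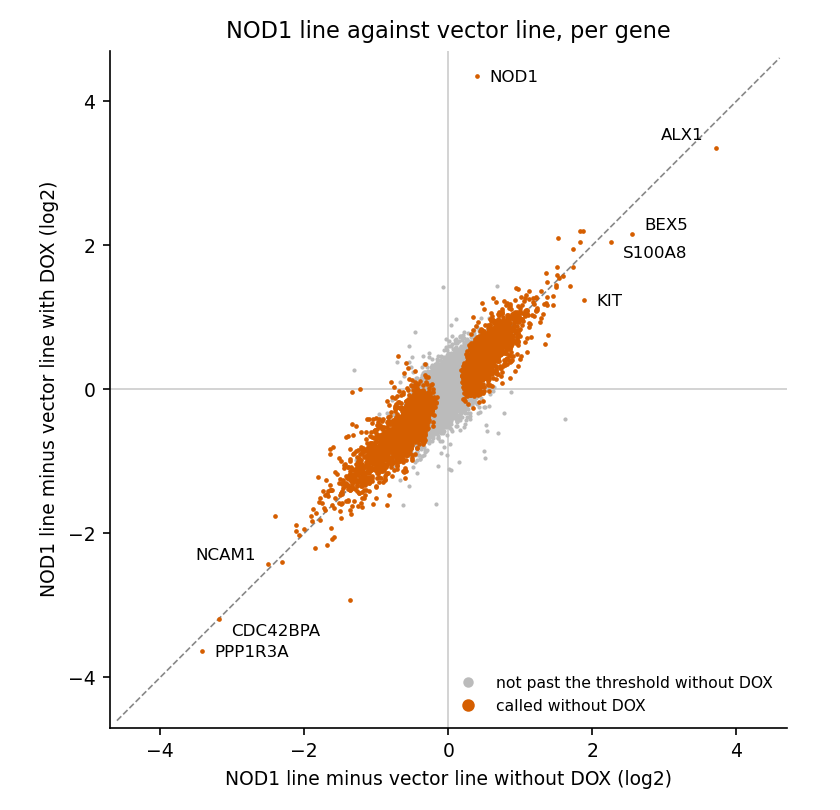
Difference between the NOD1 line and the vector line for each of 18417 genes, in log2 units, without DOX (horizontal axis) and with DOX (vertical axis). Orange points are the 4592 genes called without DOX, grey points the rest, and the dashed line marks equal values; the differences correlate at r = 0.871 and NOD1 lies far above the line.

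**Figure D3:**
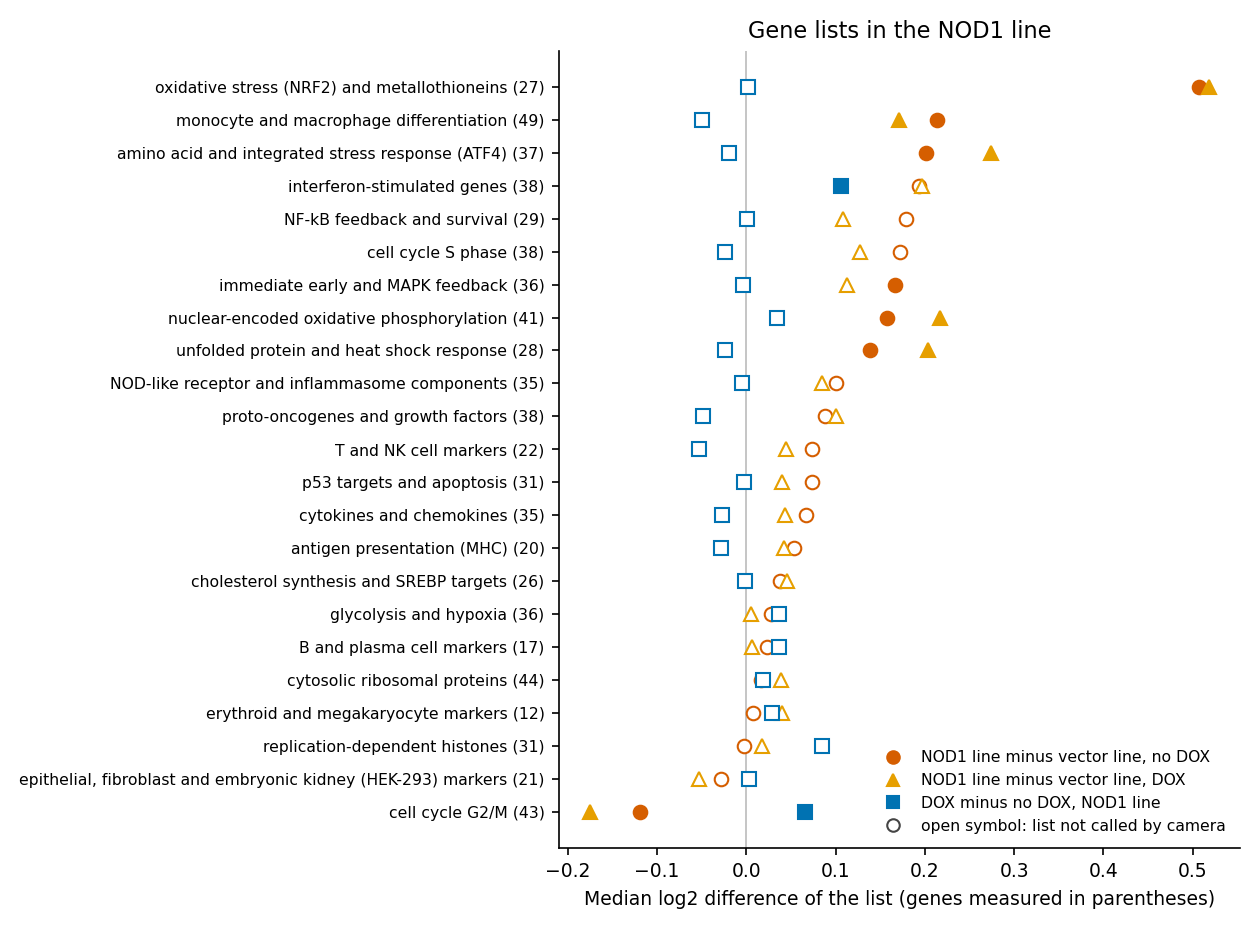
Median log2 difference of the 23 gene lists for the NOD1 line against the vector line without DOX (orange circles) and with DOX (yellow triangles) and for DOX against no DOX in the NOD1 line (blue squares). Filled symbols are lists called by camera at the preset correlation. The oxidative stress list lies at 0.51 and 0.52 in the line differences and at 0.00 for DOX.

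**Figure D4:**
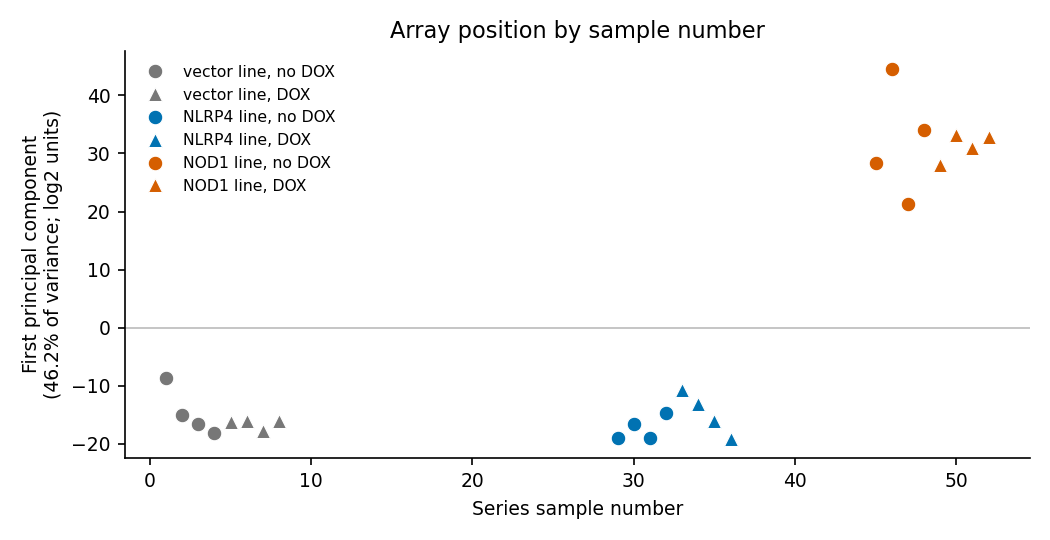
Position of the 24 arrays on the first principal component of the quantile-normalized values (vertical axis, 46.2% of the variance) by series sample number (horizontal axis). Circles are uninduced and triangles DOX-treated arrays; the 8 arrays of the NOD1 line lie between 21.2 and 44.5, and those of the vector and NLRP4 lines between −19.2 and −8.63.

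The uninduced NLRP4 line was set against the uninduced vector line in the same way. Limma called 3 genes. NLRP4 was higher, as given above, the receptor tyrosine kinase gene FLT3 rose 1.47-fold (log2 0.56, SE 0.095, adjusted p = 0.0435), and the interleukin 12 receptor gene IL12RB2 fell by 0.45 (SE 0.079, adjusted p = 0.0435). FLT3 and IL12RB2 were not called with centred arrays (0.66 and −0.41, adjusted p = 0.126 and 0.998), with only the arrays compared (adjusted p = 0.366 and 0.738) or in the values as deposited (0.61 and −0.46, adjusted p = 0.116 and 0.613), and FLT3 was not called with the array median as a covariate (0.55, adjusted p = 0.0565). With NOD1 and NLRP4 left out of the genes tested, 0 genes were called. MIER2 at 0.48 (SE 0.099, adjusted p = 0.257) and IFT20 at 0.57 (SE 0.118, adjusted p = 0.257) did not pass. Interferon-stimulated genes had a median of −0.08 over 38 genes (camera adjusted p = 0.00722, and adjusted p = 0.304 with an estimated correlation), and G2/M genes a median of −0.09 over 43 genes (camera adjusted p = 0.000657, and adjusted p = 0.164 with an estimated correlation). Of either list 0 members were called over all genes and 0 when adjusted over the list alone. The G2/M list was not called with centred arrays (camera adjusted p = 0.264), and the list count fell from 2 to 1 without vector_noDOX replicate 3 or 4. The gene count was 0 in the values as deposited, with only the arrays compared, with all probe sets by ID, and without vector_noDOX replicate 2, 3 or 4 or NLRP4_noDOX replicate 3 or 4, and 1 without NLRP4_noDOX replicate 1 or 2, and 914 genes, 4.96%, reached an unadjusted p under 0.05. On the DOX arrays the same lines gave 7 called genes, among them CD36, a scavenger receptor gene, which was lower in the NLRP4 line (−0.81, SE 0.096, adjusted p = 0.000141). There 10 lists were called, 6 upward and 4 downward, and 2 kept their call with an estimated correlation: G2/M (median −0.12, camera adjusted p = 9.37e-09, and adjusted p = 0.00589 with an estimated correlation) and oxidative stress genes (median −0.07, camera adjusted p = 0.00084, and adjusted p = 0.0376 with an estimated correlation). Of their members 0 were called over all genes, and 0 and 3 (all lower) when adjusted over the list alone.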

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

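The tests chosen only after the result was seen were that of a steady drift along the sample numbering, the comparison with the DOX arrays and the splits with NOD1 and NLRP4 left out of the genes tested.

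The difference of 4592 genes between the uninduced NOD1 and vector lines is the pattern weighed first. Mean array brightness hardly differed between the groups, with deposited medians of 8.56 ± 0.209 (SD, n = 4) in the NOD1 line and 8.52 ± 0.325 (SD, n = 4) in the vector line. With each array's deposited median as a covariate 4787 genes were called. As the group means were so close, the covariate could hardly have lowered the count, and it adds little. A steady drift along the sample numbering would place the uninduced NLRP4 arrays 0.636 of the way from the vector to the NOD1 arrays, and their mean place was −0.0468 (SD 0.0411, n = 4). Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, called as many genes, and the highest other called 2126. A step between the NOD1 wells and all others, such as separate handling, and a lasting difference between separately transduced lines cannot be told apart in this design.

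The genes called with DOX in the NOD1 line were weighed next. Besides NOD1 only KLHL5 was called, and 9 of 35 splits of the 8 arrays called at least 2 genes, the highest other 14, and with NOD1 and NLRP4 left out of the genes tested 16 of 35 called at least the 1 that remained, so chance is not excluded for KLHL5. The NOD1 rise itself has the smallest exact permutation p the design allows, 0.0286. In the NLRP4 line 1 of 35 splits, the real one, called 3 genes, and it was also the 1 that called the 2 genes left without NOD1 and NLRP4, where the highest other called 0. The real split there also separates bright from dim arrays, with deposited medians of 8.75 to 8.85 with DOX and 8.32 to 8.53 without. With the array median as a covariate HSD3BP4 and METTL23 were not called (limma adjusted p = 0.476 for both), so DOX and brightness are not told apart for them. In the vector line the real split called 0 genes and so did each of the others, so the count of 35 of 35 says nothing on chance.

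For the differences between DOX effects, 12 of 100 splits within both lines called as many genes as the 1 found for the NOD1 line minus the vector line, 7 of 100 as many as the 1 for the NLRP4 line minus the vector line, and 4 of 100 as many as the 2 for the NOD1 line minus the NLRP4 line, where the highest other split called 6. These genes were the induced NOD1 and NLRP4, for which such counts say nothing on chance, and without them 0 genes were called for all 3 differences. For the uninduced NLRP4 line against the vector line 1 of 35 splits, the real one, called 3 genes, and the highest other called 2, but without NOD1 and NLRP4 the real split called 0, so chance is not excluded for FLT3 and IL12RB2.

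Effects of DOX that differed between lines by the test of the difference itself were NOD1, by 3.95 for the NOD1 minus the vector line and 3.79 for the NOD1 minus the NLRP4 line, and NLRP4, by 3.71 for the NLRP4 minus the vector line and −3.84 for the NOD1 minus the NLRP4 line. The list medians that differed were those of G2/M genes (0.083) and cholesterol synthesis genes (−0.159), both for the NOD1 minus the NLRP4 line. Neither was called with an estimated correlation (adjusted p = 0.521 for both) or without the 4 dimmest arrays (camera adjusted p = 0.132 and 0.131).

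Single arrays far from the other 3 of their group, by the gap to the nearest relative to the whole range, were found in 5 of 120 tests, where chance alone gives about 6. The deposited median of NLRP4_noDOX replicate 1 was 8.32, against 8.51 to 8.53 in the others. PELO stood at 9.21 in vector_noDOX replicate 2 against 10.25 to 10.34, MANF at 12.44 in vector_noDOX replicate 1 against 12.01, AKR1C1 at 9.20 in NOD1_noDOX replicate 1 against 9.85 to 9.90, and TLR4 at 9.45 in vector_noDOX replicate 1 against 10.06 to 10.12.

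Among 14880 probe sets outside the genes tested, which have several gene symbols, none, or a gene represented by another probe set, limma called 2176 for the uninduced NOD1 line against the vector line, 1047 higher and 1129 lower, and 408 of them carry several gene symbols. DOX called 3 of these probe sets in the NLRP4 line, 1 in the NOD1 line and 0 in the vector line.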

How the results depend on the processing

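Alternatives chosen only after the data were seen were the values as deposited, quantile normalization over all probe sets, the array median as a covariate, leaving out the 4 dimmest arrays, the same lines on the DOX arrays and the NLRP4 line as the comparator. The values as deposited became one when quantile normalization of the gene table, itself planned as an alternative, was made the main setting. No paired analysis was possible because the labels number the samples consecutively and share no replicate number between groups. The low end of the signal limits what can be seen: NLRP4 in lines without its cassette lay at the 11.8th to 13.4th percentile of genes. The cause of the changes below was not tested, except that fewer genes, arrays or a stricter cut leave fewer calls by construction.

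Over the settings other than those named below the count for the uninduced NOD1 line against the vector line stayed between 3154 and 5468. It was 7097 with all probe sets by ID, 1816 at an adjusted p under 0.05 and at least 1.5-fold, and 2791 with treat against 1.1-fold, and it ran from 3778 to 4779 when an array was left out. Of the 51 genes other than NOD1 that the rule for named genes took for it, all kept their call in the settings run on them except 4 (MCL1, UQCRC2, NDUFB10 and PDIA4) with arrays centred on their medians and 1 (DUSP6) on the DOX arrays. With the NLRP4 line as the comparator 11 lists were called and 2 kept their call with an estimated correlation, against 7 and 5 with the vector line. Of all values for named genes other than NOD1 and NLRP4 under other settings, 1237 kept their side of the threshold, 46 lost their call and 13 gained one. List values were tallied only for the 7 lists called for the uninduced NOD1 line against the vector line. None of these could gain a call, and 93 values kept it and 5 lost it. The list counts of the other comparisons are given below.

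The count for DOX in the NLRP4 line fell from 3 to 1 above the median gene, at an adjusted p under 0.01, with treat against 1.1-fold, with only the arrays compared, in the values as deposited and without the 4 dimmest arrays, and rose to 6 with each array centred on its median. For DOX in the NOD1 line it fell from 2 to 1 with only the arrays compared, in the values as deposited and without the 4 dimmest arrays. For DOX in the vector line it was 1 with array weights. For the NLRP4 minus the vector line it was 0 above the median gene, where NLRP4 was not tested, and 2 with all probe sets by ID, with each array centred on its median, with array weights and with quantile normalization over all probe sets. For the NOD1 minus the NLRP4 line it was 1 above the median gene and 5 with all probe sets by ID. For the uninduced NLRP4 line against the vector line it was 0 with all probe sets by ID, at an adjusted p under 0.01, with treat against 1.1-fold, with only the arrays compared, in the values as deposited and without the 4 dimmest arrays, 1 with each array centred on its median and at 1.5-fold, and 7 with the same lines on the DOX arrays.

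NOD1 in the uninduced NOD1 line was 0.38 with each array centred on its median (adjusted p = 0.0567). NLRP4 in the uninduced NLRP4 line was 1.17 with only the arrays compared (adjusted p = 0.529) and 1.05 in the values as deposited (adjusted p = 0.659). NLRP4 with DOX in the NOD1 line, at 0.00, was near 0 on either side: −0.000729 with the average of the probe sets of a gene, −0.0425 with each array centred on its median and −0.0875 in the values as deposited.

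The number of lists called for DOX in the vector line, 0, was 3 with each array centred on its median and 3 in the values as deposited. For DOX in the NLRP4 line, 1, it was 0 with an estimated inter-gene correlation, 2 with fry, 8 with centred arrays and 9 as deposited. For DOX in the NOD1 line, 2, it was 0 with an estimated inter-gene correlation, 0 with fry and 5 as deposited. For the NOD1 minus the vector line, 0, it was 5 with centred arrays and 7 as deposited, and for the NLRP4 minus the vector line, 0, it was 6 with centred arrays and 6 as deposited. For the NOD1 minus the NLRP4 line, 2, it was 0 with an estimated inter-gene correlation, 1 with fry, 7 with centred arrays, 8 as deposited and 0 without the 4 dimmest arrays. For the uninduced NOD1 line, 7, it was 17 with fry, and for the uninduced NLRP4 line, 2, it was 0 with an estimated inter-gene correlation, 0 with fry and 10 as deposited.

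With an array left out, gene counts ran from 0 to 0 for DOX in the vector line, 1 to 8 in the NLRP4 line and 2 to 8 in the NOD1 line, 1 to 2, 1 to 1 and 2 to 4 for the NOD1 minus vector, NLRP4 minus vector and NOD1 minus NLRP4 lines, and 0 to 2 for the uninduced NLRP4 line. List counts ran from 0 to 1, 1 to 3 and 1 to 3 for DOX in the vector, NLRP4 and NOD1 lines, 0 to 2, 0 to 1 and 0 to 3 for the differences in the same order as above, 6 to 8 for the uninduced NOD1 line and 1 to 3 for the uninduced NLRP4 line. NOD1 ran from −0.0246 to 0.16 with DOX in the vector line, 0.16 to 0.32 in the NLRP4 line and 3.94 to 4.07 in the NOD1 line, and from 0.35 to 0.48 in the uninduced NOD1 line. NLRP4 ran from −0.0136 to 0.25 with DOX in the vector line, 3.70 to 4.01 in the NLRP4 line and −0.12 to 0.10 in the NOD1 line, and from 1.00 to 1.31 in the uninduced NLRP4 line.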

Other observations

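The test chosen only after the result was seen was the comparison with the DOX arrays. Members of lists that were not called, and genes of the DOX arrays, are given here as chosen after their values were seen.

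Glycolysis and hypoxia genes split in the uninduced NOD1 line, where 8 of 36 were higher and 10 lower than in the vector line over all genes, and 10 and 11 when adjusted over the list alone (median 0.03, camera adjusted p = 0.841). The mitophagy receptor genes BNIP3 (−1.34, SE 0.157, adjusted p = 9.43e-07) and BNIP3L (−1.22, SE 0.163, adjusted p = 5.22e-06) and the pyruvate dehydrogenase kinase gene PDK1 (−1.14, SE 0.169, adjusted p = 1.77e-05) were lower. The glycolytic enzyme genes ALDOA (0.83, SE 0.114, adjusted p = 7.80e-06) and ENO1 (0.79, SE 0.138, adjusted p = 0.000116) and the glucose transporter gene SLC2A1 (0.87, SE 0.134, adjusted p = 2.99e-05) were higher. NOD-like receptor and inflammasome genes split as well: the inflammatory protease gene CASP1 (0.87, SE 0.160, adjusted p = 0.000214) and the inflammasome adaptor gene PYCARD (0.57, SE 0.128, adjusted p = 0.00147) were higher, and the NOD2 partner gene ERBIN (−0.96, SE 0.143, adjusted p = 1.89e-05) and the flagellin sensor component NAIP (−0.69, SE 0.139, adjusted p = 0.000559) were lower.

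With DOX, the NLRP4 line differed from the vector line in 7 genes, 2 higher and 5 lower. Besides NLRP4 and CD36 they included NCAM2 (0.64, SE 0.116, adjusted p = 0.0380), the NF-kB inhibitor TNFAIP3 (−0.61, SE 0.114, adjusted p = 0.0478) and the lysosomal membrane protein gene SCARB2 (−0.53, SE 0.086, adjusted p = 0.0181). FLT3 stood at 0.44 (SE 0.096, adjusted p = 0.170) and IL12RB2 at −0.30 (SE 0.079, adjusted p = 0.414) there and were not called.

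A hypothesis of a response to the NOD1 level was tested, in which the genes that differ at the 1.32-fold higher uninduced level would move further the same way when DOX raises NOD1 16.2-fold. The slope of the DOX change in the NOD1 line on the line difference was −0.0136 over genes, with different uninduced arrays on either side and an SD of 0.0771 over all 70 relabelings of the 8 arrays of that line, so the slope plus 2 SD, 0.141, lay under the bound of 0.2 set beforehand. No growth of the line differences within 6 h of induction was found, but a slope up to 0.141 is not excluded. The slope was taken over all 18416 genes other than NOD1, called or not, and the DOX change of the vector line was not subtracted. Noise in the line difference also shrinks such a slope. A response already complete at the uninduced level or slower than 6 h was not tested.

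A hypothesis of different copy numbers of chromosome segments between the lines was tested on 17218 windows of 51 neighbouring genes. Medians of at least 0.3 in size were found in 0.598% of windows for the uninduced NOD1 line against the vector line, below the 1% set beforehand as the bound against it, but in 0% in any of 1000 shuffles of the gene order. Window medians ran from −0.398 to 0.411, at most 0.245 in size in the shuffles, and differences of adjacent genes correlated at 0.243, against 0.0467 for the NLRP4 line. Whole chromosomes shifted by less than the cut of 0.3. Their medians ran from −0.07 on chromosome 18, with 12 genes called higher and 56 lower, to 0.14 on chromosome 16. On the latter 194 genes were higher and 15 lower, and its median was 0.12 on the DOX arrays. The cut was therefore too high to decide, and changed copy number stays open beside transcript length and base composition, which also go with gene neighbourhoods and were not tested.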
